A study of Capra hircus with 3 samples.

How the data were processed

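The files hold droplet single-cell RNA counts from 3 libraries labelled as goat fetal testis at E85, E105 and E125. There is 1 library per stage and there are no replicates. The values are raw UMI counts per feature and barcode, deposited as filtered matrices and made by the submitters with Cell Ranger. The version is 3.1 per the submitters' processing notes and 6.0.0 per the file headers. The genome build and annotation behind the counts are not given in the sources used here, so features are named only by the symbols that the files pair with them. Of 27271 features 16616 had a symbol and 10655 had none, and features with a symbol held 60.5% of the UMIs. The reference gene table matched 0 of the features without a symbol. Listed genes were looked up by symbol or by a synonym of that table, whose assembly is ARS1.2.

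Barcodes were kept with at least 1000 UMIs, at least 500 genes and at most 20% of UMIs from 13 mitochondrial genes, which left 6328, 7069 and 7319 barcodes for E85, E105 and E125. Barcodes above the mitochondrial limit numbered 683, 1032 and 409. Doublets were called within each library by a rewrite of the Scrublet method with an expected rate of 6%, and 175, 141 and 2 were removed (2.77%, 1.99% and 0.03%). The caller did not work in the library labelled E125, so an alternative that removes the top 6% of scores in each library was added after seeing the data. Counts of each cell were scaled to 10000 and log-transformed. The 3000 most variable genes, 30 principal components, 15 nearest neighbours and Leiden clustering at resolution 1 gave 36 clusters of all libraries together, without integration. A cluster took the name of a cell type with at least 3 of its markers detected and a mean log2 fold of the markers of at least 0.3. Detected means at least 2 times the mean of the other clusters and found in at least 10% of the cells. Where several types qualified, the type with most markers among the 10 leading genes was taken first. A cluster stayed unnamed if another type had more markers among those genes, or if it had none there and few UMIs per cell. Folds had a pseudocount of 0.1. Clusters that met no rule were left unnamed, and 1 cluster is named ZP3/FIGLA-led after its leading genes. Cluster 27 met the marker rule for macrophages but was led by CLEC9A, and it was also left unnamed. Names end in "-like" because they rest on RNA alone.

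UMIs of a class were summed per library and given as CPM. Intervals are exact at 95%: Clopper-Pearson for shares, Poisson for levels, and the binomial split of both sums for ratios. A count of 0 is given the limit of 3 counts. Classes were compared where both libraries held at least 50 cells. Gene lists, written before the data were examined, were summarised by the median log2 CPM ratio of members with at least 20 UMIs over both libraries, with a prior of 0.5 UMI and at least 5 members. Each median has an interval from 1000 Poisson draws and a percentile among 10000 random lists of equal size matched in 20 expression bins. The percentile describes these libraries and is not a test. For shares of cells with proliferation genes, cells were thinned to the 10th percentile of UMIs of the class, rounded down. No p-value was computed, because cells of 1 library are not replicates.

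Genes were named by a rule set before the data were examined. Candidates had a symbol, at least 50 CPM in either library and no other class with more than 10 times the level in the library where the gene was higher, which guards against free RNA. They were not ribosomal-protein, mitochondrial or haemoglobin genes. They were ranked by the interval bound nearest 1, and up to 4 members of each list were added. In germ-like cells 37 genes were left out as free RNA and 2643 candidates remained, and in Sertoli-like cells 23 were left out and 1429 remained. Markers of class identity are named besides.

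Some steps departed from the plan. The plan put E125 against E85 first, but germ-like and Sertoli-like cells were too few in the library labelled E125, so the rule was applied to E105 against E85 for them and to both contrasts for the other classes. The ZP3/FIGLA-led cluster met the marker rule for germ cells and would have been named germ by the plan. It was set apart after its leading genes were seen, so germ-like cells in the library labelled E125 number 0 by that choice and 122 by the plan. Unnamed clusters also served as sources of free RNA. The thinning depth of germ-like cells was taken over the libraries that hold them. MKI67 was planned as a measure but no feature has that symbol. Comparisons across all classes, the level of AMH by cluster, the levels of classes under other clusterings and TOP2A at 4600 UMIs were chosen after seeing the data.

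The gene and list steps were tested on simulated data. Counts were Poisson draws for the genes of germ-like and Sertoli-like cells at E105 against E85. The intervals assume the same model, so cover near 95% follows from it. Variation between cells, animals or libraries was not simulated. In the 8589 germ-like genes the interval covered 96.1% of unchanged ratios, and it excluded 1 for 90.0% of genes changed by 2-fold and for 100.0% of those changed by 4-fold. In the 9276 Sertoli-like genes these shares were 95.8%, 94.0% and 100.0%. Of simulated lists without change 8.0% and 4.0% fell outside the central 95% of random lists, and all lists changed by 2-fold lay above it. In the changed lists every member was changed by 2-fold. Smaller shifts and lists of mixed members, as in the results below, were not simulated.

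Alternatives changed 1 choice at a time. They were no cell filter, a stricter filter (3000 UMIs, 1000 genes, 10% mitochondrial), doublets kept, Leiden resolution 0.5 and 2, each library clustered on its own, TMM scaling, CPM without mitochondrial, ribosomal-protein and haemoglobin genes, the mean over cells, cells thinned to a fixed number of UMIs, other minimum counts, and for proliferation other thresholds and no thinning. Clustering without the library labelled E125 was also added after seeing the data. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, scikit-image 0.26.0, igraph 0.11.9, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3. TMM factors came from edgeR 4.0.16, which was used for nothing else.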

Results

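Droplet single-cell RNA sequencing had been run on samples labelled as fetal testis of the domestic goat (Capra hircus). The libraries are named by embryonic day, E85, E105 and E125, with 1 library per stage. The series title places the work around the mitotic arrest of male germ cells before birth, and the question each comparison addresses is how germ cells and their somatic neighbours differ between these stages. The deposited matrices held 7478 barcodes and 45339231 unique molecular identifiers (UMIs) for E85, 8520 barcodes and 40741902 UMIs for E105, and 8346 barcodes and 49692252 UMIs for E125. The median barcode had 3320.5, 2608 and 3043.5 UMIs, in the same order. After filtering and removal of called doublets 6153, 6928 and 7317 cells remained. Every stage is a single library, so no difference below has a replicate check or a test. Levels are UMIs of a gene divided by all UMIs of the class and given as counts per 10⁶ (CPM). Ratios, levels and shares carry exact 95% intervals that cover counting error only.

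Sertoli-like cells, the somatic cells that enclose fetal germ cells, made up 40.4% of E85 cells (39.2 to 41.7) and 29.3% of E105 cells (28.2 to 30.4). Germ-like cells made up 4.03% (3.55 to 4.55; 248 cells) and 1.39% (1.12 to 1.69; 96 cells). Stromal-like cells accounted for 37.2% at E85 and 50.5% at E105, endothelial-like cells for 4.88% and 3.83%, lymphoid-like cells for 6.06% and 8.34%, macrophage-like cells for 1.74% and 2.05%, and mural-like cells, which wrap small vessels, for 1.25% and 1.13%. Leydig-like cells, the source of fetal androgen, were few, with 20 cells at E85 and 26 at E105. No cluster took the name of peritubular myoid cells. Barcode filters act on these shares, because stromal-like cells had a median of 2034 UMIs at E85 and Sertoli-like cells 10191. With a stricter filter the Sertoli-like share was 68.9% at E85 and 55.7% at E105, and the stromal-like share 6.77% and 17.6%.

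The library labelled E125 held another set of cells. Its germ-like class had 0 of 7317 cells, which allows a share of up to 0.041%, and its Sertoli-like class had 30 cells (0.410%, 0.277 to 0.585). With each library clustered on its own the class was 6.22% of it, 455 cells of which 258 came from cluster 33 and 165 from the mesothelial-like class, with 76.0 CPM of SOX9 (68.9 to 83.65) against 328 CPM at E85. Of these 30 cells 29 fell in a cluster of cycling cells, cluster 6, where they carried 2.59 CPM of SOX9 (0.0656 to 14.4), the transcription factor of Sertoli cell fate, against 361 CPM in the E85 cells of that cluster. The same 29 cells carried 3079 CPM of FST, the activin antagonist follistatin, which had 0 UMIs in the E85 and E105 cells of cluster 6. A cluster led by ZP3 and FIGLA, a zona pellucida gene and a transcription factor of oocytes, held 122 cells or 1.67% of this library (1.39 to 1.99), 2 cells at E105 and 0 at E85. This cluster also met the marker rule for germ cells, and it was kept apart from the germ-like class after its leading genes were seen, so the 0 above counts germ-like cells of the kind found at E85 and E105. The ZP3/FIGLA-led cells had a median of 74464 UMIs. A further 615 cells formed an unnamed cluster led by KCNK12, FST and HSD17B1 that drew 8.40% of the library labelled E125 and no cell of the others. Stromal-like cells made up 68.2% of this library (20.3% with each library clustered on its own), endothelial-like cells 11.2%, mural-like cells 1.91%, lymphoid-like cells 1.46% and macrophage-like cells 1.07%. Mesothelial-like cells (3.99%) and neural or Schwann-like cells (1.11%) were found there alone, where 0 cells allow up to 0.0488% at E85 and 0.0433% at E105.

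**Figure D1:**
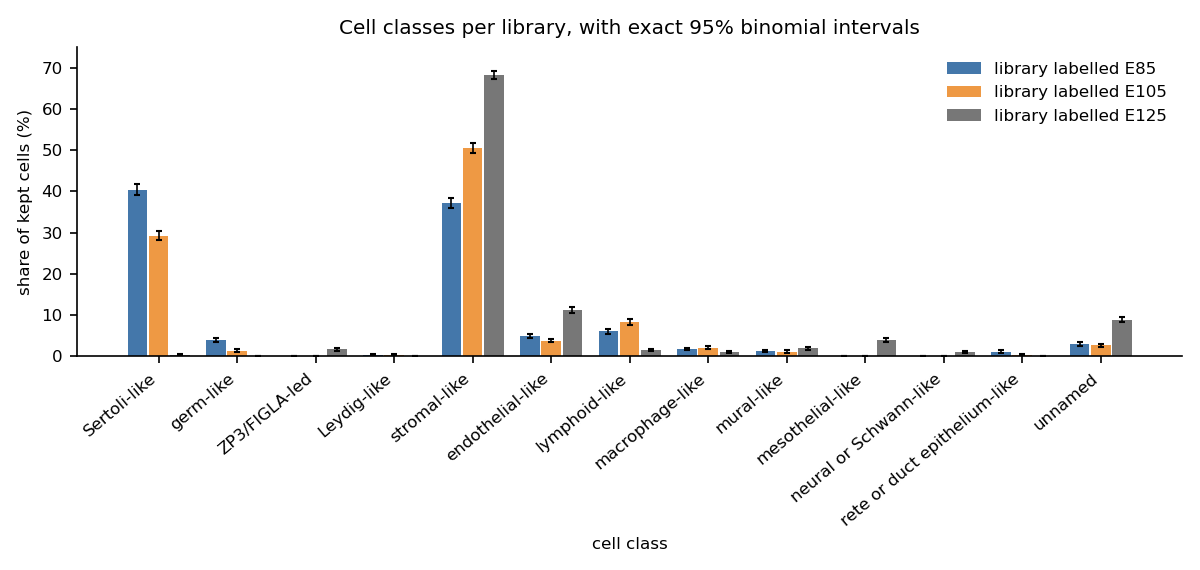
Share of kept cells (%, vertical axis) in each cell class (horizontal axis) for the libraries labelled E85, E105 and E125, with exact 95% binomial intervals as error bars. Sertoli-like cells stand at 40.4%, 29.3% and 0.410%, and stromal-like cells at 37.2%, 50.5% and 68.2%.

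Sex-typical genes also set the library labelled E125 apart when all cells of a library were pooled. AMH, the hormone that removes the female duct in males, stood at 1393 CPM at E85, 3787 CPM at E105 and 31.6 CPM in the library labelled E125. SOX9 stood at 221, 179 and 25.0 CPM and DMRT1, a factor of male gonadal fate, at 121, 96.1 and 9.72 CPM. INSL3, the Leydig cell hormone of testicular descent, stood at 11.2, 34.5 and 0.665 CPM. These 4 genes were lowest in the library labelled E125. ZP3 and FIGLA were highest there, with 1.20, 2.56 and 2110 CPM for ZP3 and 1.13, 0.293 and 792 CPM for FIGLA. SRY, the male-determining gene, had 4 UMIs at E85, 5 at E105 and 0 in the library labelled E125, and 0 UMIs allow up to 0.0623 CPM. DDX4, common to germ cells of both sexes, stood at 49.7, 21.7 and 26.0 CPM. The contents of this library go against its label of fetal testis, so germ-like and Sertoli-like cells are compared between E85 and E105 only.

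**Figure D2:**
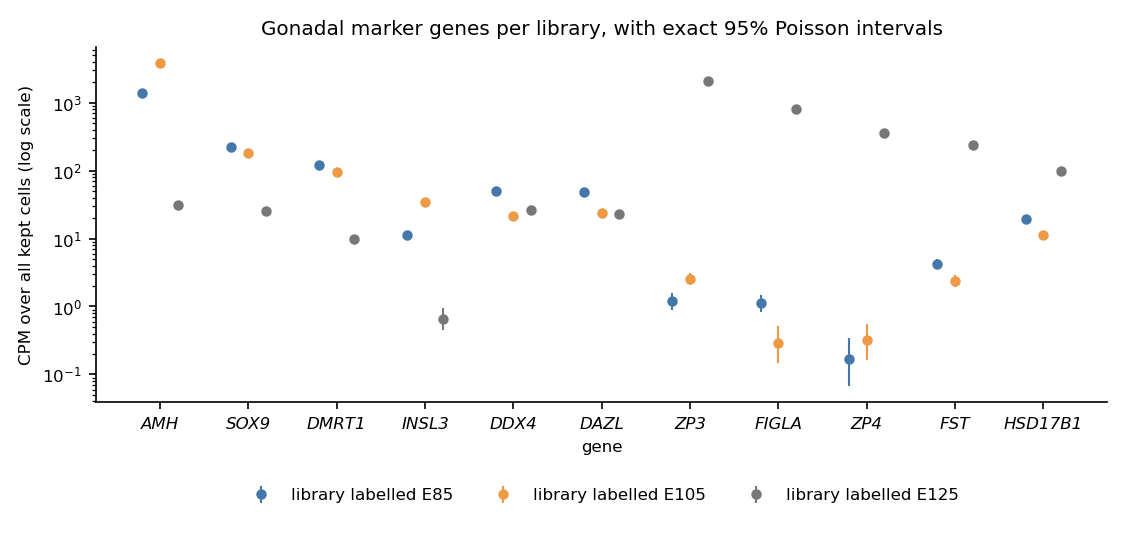
CPM over all kept cells (vertical axis, log scale) of 11 gonadal genes (horizontal axis) in the libraries labelled E85, E105 and E125, with exact 95% Poisson intervals. AMH stands at 1393, 3787 and 31.6 CPM, and ZP3 at 1.20, 2.56 and 2110 CPM.

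Germ-like cells kept their identity genes at similar levels at E85 and E105. DDX4, an RNA helicase of germ cells, stood at 419 and 418 CPM (ratio 0.998, 0.917 to 1.09), the receptor KIT at 99.2 and 100.2 CPM (ratio 1.01, 0.848 to 1.20) and the pluripotency factor POU5F1 at 13.2 and 13.4 CPM (ratio 1.01, 0.610 to 1.64). The RNA-binding factor DAZL was 1.13 times as high at E105 (1.04 to 1.22; log2 −0.07 with TMM scaling) and PIWIL4, a piRNA-guided silencing protein of fetal male germ cells, 1.27 times (1.10 to 1.47). PIWIL2 had a ratio of 0.886 (0.720 to 1.09) and NANOS3 of 1.33 (0.816 to 2.12). NANOS2 and NANOG had 4 UMIs each at E85 and 0 at E105, too few to compare. The ZP3/FIGLA-led cells of the library labelled E125 carried 112 CPM of DDX4 and 102 CPM of DAZL, 2.82 CPM of PIWIL4, and 0 UMIs of NANOS3, which allows up to 0.292 CPM.

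Cell cycle genes did not differ in a single direction between E85 and E105 germ-like cells. The cyclin-dependent kinase inhibitor CDKN1A was 3.45 times as high at E105 (17.5 to 60.5 CPM, 2.57 to 4.65), and its log2 ratio in the other classes lay between 0.34 and 0.96. CDKN2A, another inhibitor, was lower, with a ratio of 0.519 (0.350 to 0.750), and CDKN1B had a ratio of 0.943 (0.726 to 1.22). The list of CDK inhibitors and pocket proteins had a median log2 ratio of 0.16 (−0.18 to 0.36), at percentile 31.9 among 10000 random lists matched on expression. G1/S and S phase genes had a median of 0.40 (0.23 to 0.53), at percentile 98.6, with 21 of 23 measured members higher at E105. Examples were the histone mRNA binding protein SLBP with a ratio of 2.90 (2.43 to 3.48), the origin recognition gene ORC1 with 1.54 (1.15 to 2.07) and the helicase subunit MCM4 with 1.38 (1.18 to 1.61). G2/M genes had a median of 0.16 (0.11 to 0.29), at percentile 43.3. The median over all 8588 measured genes was itself 0.21 in germ-like cells, so the G2/M list lay slightly below it and the G1/S list 0.19 above it. TMM scaling, which removes most of that shift, gave −0.08 for G2/M and 0.16 for G1/S. In thinned cells the G1/S list stood at 0.18 against 0.22 for all genes, and as a mean over cells at 0.17 against 0.20, so its excess over all genes did not hold under these settings.

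Among lists of germ cell programmes, genes of undifferentiated spermatogonia, the later stem cell pool, had the highest percentile, 99.2, with a median of 0.42 (0.27 to 0.53) and 16 of 18 measured members higher at E105. LHX1 was 1.996 times as high (1.64 to 2.42), ZBTB16 1.80 times (1.42 to 2.26) and the GDNF receptor GFRA1 1.71 times (1.22 to 2.39). The 12 members that were also measured in other classes had a median of 0.40 there, and in germ-like cells they differed from it gene by gene by a median of 0.03. The other 6 had no value outside germ-like cells. TMM scaling gave 0.18 in germ-like cells. Meiosis genes had a median of 0.38 (0.12 to 0.49), at percentile 94.95, inside the central 95% of random lists. The synaptonemal complex gene SYCP2 was 1.65 times as high (1.39 to 1.96) and HORMAD1 1.57 times (1.10 to 2.24), whereas SYCP3 had a ratio of 1.29 (0.891 to 1.85) and STRA8, a gene of meiotic entry, of 1.75 (0.991 to 3.03). The other programmes also lay inside it. These were the piRNA pathway (0.19, percentile 57.0), pluripotency and early fetal germ cell genes (0.28, percentile 77.9), male germ cell fate and prospermatogonia (0.09, percentile 31.4), DNA methylation machinery (0.11, percentile 22.7) and Polycomb and histone methylation enzymes (0.26, percentile 66.2).

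Outside the lists, the genes with the greatest differences in germ-like cells included the homeobox gene IRX4, 3.71 times as high at E105 (2.68 to 5.18), the DNA repair gene XPA, 3.21 times (2.71 to 3.81), NETO2, 3.14 times (2.31 to 4.28), and PCSK1N, 3.32 times (2.96 to 3.74). PCSK1N was also higher in Sertoli-like cells, 7.13 times (6.69 to 7.62). Lower at E105 were ACAD8, a mitochondrial enzyme of valine breakdown, with a ratio of 0.391 (0.346 to 0.441), the apoptosis inhibitor BIRC2 with 0.495 (0.435 to 0.563), the glutamate transporter SLC1A6 with 0.505 (0.386 to 0.652), WDR18 with 0.521 (0.401 to 0.670) and ARHGAP32 with 0.573 (0.465 to 0.701). Markers of Sertoli cells were also higher in the E105 germ-like cells, with a median log2 ratio of 0.50 (0.41 to 0.65) over 12 measured markers.

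TOP2A, the topoisomerase of dividing cells, was found in germ-like cells at both stages, mostly at few UMIs per cell. In cells thinned to 6700 UMIs, 40.8% of E85 germ-like cells (34.3 to 47.6; 91 of 223) and 55.2% of E105 germ-like cells (44.1 to 65.9; 48 of 87) carried a UMI of TOP2A, and 6.73% (3.81 to 10.85) and 10.3% (4.84 to 18.7) a UMI of the mitotic kinase CDK1. The unthinned TOP2A shares were 67.3% and 74.0% at median depths of 18416 and 18930 UMIs, and thinning left out 25 and 9 cells. The planned share with at least 3 UMIs over the G2/M list was 100% (223 of 223) and 97.7% (85 of 87), so this measure was saturated and could not show a difference. No class lacks TOP2A, so Sertoli-like cells thinned to a common 4600 UMIs, a depth chosen after these values were seen, served as the background. At that depth TOP2A was found in 36.2% of E85 and 37.0% of E105 germ-like cells (30.0 to 42.8 and 27.1 to 47.7), against 6.81% and 8.35% of Sertoli-like cells. The germ-like cells that carried it held a mean of 2.02 and 2.03 UMIs, and the Sertoli-like ones 4.73 and 5.12. At least 5 TOP2A UMIs were found in 3.45% (1.5 to 6.68) and 3.26% (0.680 to 9.23) of germ-like cells, with intervals that include the Sertoli-like shares of 2.65% and 3.34%. Over the G2/M list the median germ-like cell held 8 and 10 UMIs, and the median Sertoli-like cell 0. The median ZP3/FIGLA-led cell of the library labelled E125 held 13, and 0.0% of those cells had at least 5 TOP2A UMIs. In germ-like cells the list may therefore not measure cycling alone. TOP2A in germ-like cells had a summed ratio of 1.12 (0.988 to 1.26) and CDK1 of 1.39 (0.899 to 2.13). The TOP2A shares of the 2 stages thus lay outside each other's intervals at 6700 UMIs and inside them at 4600, and with 1 library per stage a difference in germ cell cycling could not be tested.

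**Figure D3:**
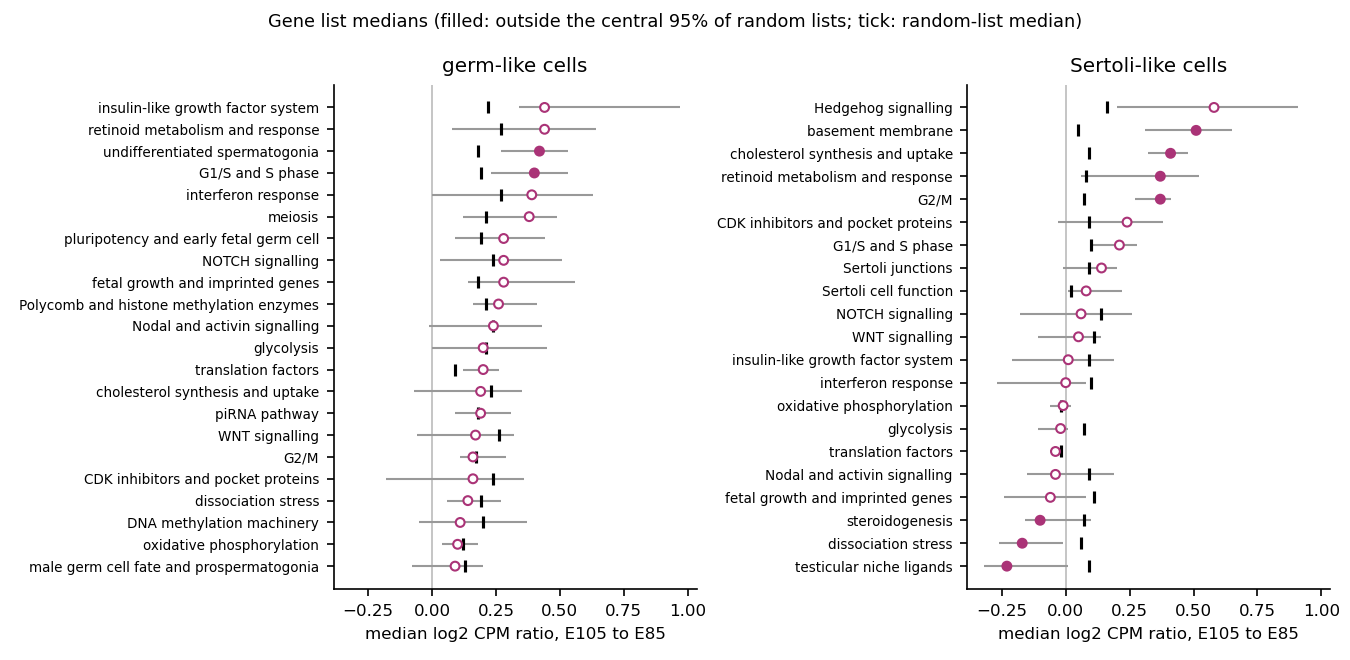
Median log2 CPM ratio, E105 to E85 (horizontal axis), of each gene list (vertical axis) in germ-like and Sertoli-like cells, with 95% intervals from 1000 Poisson draws. Filled points lie outside the central 95% of 10000 random lists and ticks mark the random-list median. In germ-like cells the G1/S list stands at 0.40 and the G2/M list at 0.16, and in Sertoli-like cells the G2/M list stands at 0.37.

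Sertoli-like cells carried more hormone RNA at E105 than at E85. AMH was 3.16 times as high at E105 (2177 to 6876 CPM, 3.13 to 3.19) and INHA, the alpha subunit of inhibin, 1.95 times (1576 to 3073 CPM, 1.925 to 1.974). SOX9 had a ratio of 0.942 (0.912 to 0.973), the FSH receptor FSHR of 1.06 (1.01 to 1.10; log2 −0.02 with TMM scaling) and the ligand DHH of 1.498 (1.099 to 2.045). The list of Sertoli cell function had a median log2 ratio of 0.08 (0.01 to 0.22), at percentile 80.7, with 13 of 21 measured members higher and AMH alone at least 2 times higher. With TMM scaling this median was −0.01. Other genes higher at E105 were the centrosomal gene TACC2 with a ratio of 11.1 (9.56 to 12.8; 7.89 to 87.1 CPM), the desmosome protein DSP with 8.78 (6.08 to 13.1), ESM1 with 5.85 (5.28 to 6.49), the retinoic acid carrier CRABP2 with 4.14 (3.90 to 4.39) and CRYBB1 with 3.38 (3.23 to 3.54). The protease inhibitor TIMP2 was 4.47 times as high (4.43 to 4.51), but it was at least 2 times higher in every other measured class as well. HSD17B3, which converts androstenedione to testosterone, was lower at E105 at 133 CPM against 265.5 CPM (ratio 0.501, 0.479 to 0.524). Also lower were ACOT8 (ratio 0.487, 0.459 to 0.516), MGARP (0.499, 0.463 to 0.538), CSRP2 (0.547, 0.523 to 0.571) and BAMBI, a decoy receptor of TGF-beta signalling (0.554, 0.515 to 0.596).

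G2/M, cholesterol and basement membrane lists were higher in E105 Sertoli-like cells. G2/M genes had a median of 0.37 (0.27 to 0.41), at percentile 100, with 24 of 25 measured members higher, among them CKAP2 with a ratio of 1.419 (1.343 to 1.498), KIF11 with 1.45 (1.26 to 1.66) and TOP2A with 1.32 (1.25 to 1.39). G1/S and S phase genes stood at 0.21 (0.10 to 0.28), inside the central 95% of random lists. The share of cells with at least 3 G2/M UMIs was 9.29% at E85 (8.14 to 10.5) and 11.3% at E105 (9.83 to 12.9) at 4600 UMIs, and 17.4% and 17.9% unthinned. Cholesterol synthesis and uptake had a median of 0.41 (0.32 to 0.48), at percentile 100, with 21 of 24 members higher, including MSMO1 (ratio 1.57, 1.49 to 1.66) and IDI1 (1.474, 1.401 to 1.552), and with MVK lower (0.693, 0.610 to 0.785). The same list stood at 0.34 in the other classes, a median gene-by-gene difference of 0.05 over 23 shared members. Basement membrane genes had a median of 0.51 (0.31 to 0.65), at percentile 99.9, with 9 of 10 members higher, such as the laminin LAMB2 (ratio 1.99, 1.84 to 2.15) and the perlecan gene HSPG2 (1.83, 1.38 to 2.43). Stromal markers, a reading of free RNA or mixed cells, were higher by as much in the same cells (0.54, 0.26 to 0.77). The basement membrane list stood at 0.16 in the other classes, a gene-by-gene difference of 0.23. Retinoid metabolism and response had a median of 0.37 (0.06 to 0.52), at percentile 98.7, and of 0.30 in the other classes (gene-by-gene difference −0.02 over 10 members). The testicular niche ligands, a list drawn up for several somatic classes and not for Sertoli cells alone, had a median of −0.23 (−0.32 to 0.01), at percentile 0.04. TGFB2 among them had a ratio of 0.620 (0.540 to 0.710). Steroidogenesis genes stood at −0.10 (−0.16 to 0.10), at percentile 2.11. Sertoli junctions (0.14, percentile 67.3), NOTCH signalling (0.06, percentile 25.7), WNT signalling (0.05, percentile 29.8) and glycolysis (−0.02, percentile 18.3) lay inside the central 95% of random lists. The dissociation stress list, a sign of handling, was lower in E105 Sertoli-like cells, at −0.17 (−0.26 to −0.01). Germ cell markers in Sertoli-like cells had a median of −0.92 (−1.21 to −0.32) and macrophage markers of −0.91 (−1.23 to −0.41), although the share of macrophage-like cells was not lower at E105.

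Leydig-like cells were under the 50 needed for a comparison in each library, so only their levels are given. INSL3 stood at 1271 CPM at E85 (1089 to 1473) and 3781 CPM at E105 (3530 to 4045), and the cholesterol carrier STAR at 799 CPM (656 to 963) and 713 CPM (607 to 833). The 5 cells of the library labelled E125 had 310 CPM of INSL3 (186 to 484) and 293 CPM of STAR (174 to 464).

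Stromal-like cells were dominated by different clusters in the 3 libraries. Cluster 1, led by CCN3 and DLK1, held 1846 cells at E85 and 1421 at E105, and cluster 20, led by TAC1 and NTRK2, held 144 and 1711. In the library labelled E125 clusters 30, led by COL12A1 and MGP, with 3078 cells, and 31, led by CHODL, with 1529 cells, held most of the class, and neither had a cell from E85 or E105. At E105 against E85 the collagen and fibrillar matrix list had a median of 0.68 (0.43 to 0.70), at percentile 100, with 21 of 24 measured members higher and 7 at least 2 times. Over the 20 members also measured in other classes the median there was 0.24, and the gene-by-gene difference of stromal-like cells from them 0.10. With at least 100 UMIs per member the stromal-like median was 0.38. Smooth muscle contraction genes stood at 0.34 (0.22 to 0.52), with a median of 0.34 in the other classes and a gene-by-gene difference of 0.23, and the insulin-like growth factor system at 0.34 (0.18 to 0.54). Markers of other types moved in the same cells, with medians of 0.49 (0.38 to 0.58) for myoid, −0.90 (−1.53 to −0.41) for germ cell, −0.39 (−0.62 to 0.02) for Sertoli cell and −0.33 (−0.71 to 0.00) for macrophage markers. G2/M genes were lower, at −0.20 (−0.28 to −0.13), with 21 of 25 members lower, while G1/S and S phase genes stood at 0.08 (−0.10 to 0.12). The share of cells with at least 3 G2/M UMIs at 1400 UMIs was 7.40% at E85 and 5.67% at E105 (unthinned 8.17% and 6.83%). NEFL, a neurofilament gene, was 13.25 times as high at E105 (8.655 to 21.35), lipoprotein lipase LPL 4.60 times (3.465 to 6.205) and the BMP target ID1 4.27 times (3.51 to 5.24). CDH18 had a ratio of 0.417 (0.343 to 0.506) and LIMCH1 of 0.442 (0.375 to 0.520).

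Stromal-like cells of the library labelled E125 differed far more from those of E85. The collagen and fibrillar matrix list stood at 1.10 (0.99 to 1.17), with 14 of 27 members at least 2 times higher and 4 at least 2 times lower, and at 1.58 in the other classes (gene-by-gene difference −0.67 over 22 members). It lay between 0.93 and 1.66 under the alternatives. WNT signalling had a median of 1.92 (1.31 to 2.23), at percentile 100, and retinoid metabolism and response of 1.41 (1.07 to 1.70). Over the 13 and 11 members also measured in other classes, the medians there were 0.98 and 1.41, and gene by gene stromal-like cells lay below them by 0.53 and 0.57. Fetal growth and imprinted genes were lower at −1.23 (−1.46 to −1.05) and G1/S and S phase genes at −0.80 (−0.98 to −0.55), with G2/M genes at −0.06 (−0.15 to 0.05). ANO4, a calcium-regulated membrane protein, had a ratio of 377 (104 to 3118) on 2 UMIs at E85. The matrix protein POSTN had a ratio of 0.0357 (0.0320 to 0.0396), SCIN of 0.0303 (0.0214 to 0.0418) and TEK of 0.0210 (0.0123 to 0.0339). Genes that lead clusters found almost wholly on 1 side of this contrast restate the cluster split. Examples are MGP of cluster 30, with a ratio of 116.5 (92.6 to 149), and SHOX2 of clusters 1 and 15, with 0.00925 (0.00755 to 0.0112). The dissociation stress list was higher in this library's stromal-like cells, at 0.76 (0.34 to 0.90). Macrophage markers in the same cells stood at −3.49 (−4.05 to −2.93) over 6 genes and mesothelial markers at 2.39 (1.27 to 3.1) over 5.

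Endothelial-like cells were mostly in cluster 17, led by PNOC and VWF, at E85 and E105 (210 and 172 cells), and in cluster 5, led by CA4, in the library labelled E125 (697 cells). At E105 against E85 G2/M genes had a median of 0.51 (0.36 to 0.63), with 22 of 23 members higher, whereas G1/S and S phase genes stood at −0.18 (−0.35 to 0.03), at percentile 0.29, with 10 of 17 lower. Basement membrane genes had a median of 0.52 (0.36 to 0.61). The interferon response list stood at 0.42 (0.23 to 0.55), with all 17 measured members higher, and the dissociation stress list at 0.31 (0.01 to 0.49). Stromal markers (0.58, 0.30 to 0.79) and Sertoli markers (0.52, 0.24 to 0.89) were higher in these cells too. The share of cells with at least 3 G2/M UMIs at 1900 UMIs was 10.3% (6.98 to 14.6) at E85 and 11.2% (7.60 to 15.8) at E105, and 48 of 300 and 50 of 265 cells unthinned. CAPG was 31.1 times as high (14.9 to 78.4) and C1QTNF5 5.21 times (3.64 to 7.63), while TGM2 had a ratio of 0.375 (0.254 to 0.542). In the library labelled E125 against E85, basement membrane genes stood at 1.28 (0.98 to 1.51), NOTCH signalling at 0.96 (0.82 to 1.31), the interferon response at 1.03 (0.70 to 1.21) and the list of endothelial function at 0.05 (−0.09 to 0.16). CYP26B1, which degrades retinoic acid, was 35.1 times as high (19.04 to 73.4) and ID1, which also leads cluster 5, 25.8 times (22.3 to 30.05). PRCP had a ratio of 0.238 (0.202 to 0.280) and CRABP1 of 0.246 (0.212 to 0.285). Stromal markers in endothelial-like cells, again a reading of free RNA or mixed cells, were higher by a median of 2.21 (1.98 to 2.56). Myoid markers were higher by 1.77 (0.76 to 2.99) and mural markers by 1.53 (0.91 to 3.46).

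Macrophage-like cells formed 1 cluster across the libraries. At E105 against E85 the macrophage function list had a median of 0.29 (0.10 to 0.38), at percentile 98.7. SALL1, a factor of microglia, had a ratio of 26.6 (4.45 to 1081) on 1 UMI at E85 and the cytokine gene IL18 of 5.94 (2.83 to 14.4). SPP1, encoding osteopontin, had a ratio of 0.196 (0.168 to 0.227), F13A1 of 0.0749 (0.0377 to 0.135) and the chemokine CCL17 of 0.0912 (0.0320 to 0.212), and S100A12 had 86.8 CPM at E85 and 0 UMIs at E105, at least 14.5-fold lower against a floor of 3 counts over the class (log2 −0.55 with each library clustered on its own). In the library labelled E125 SPP1 had a ratio to E85 of 0.0175 (0.00931 to 0.0302), the interferon-induced chemokine CXCL9 of 0.0271 (0.0178 to 0.0397) and PLAC8 of 0.106 (0.0653 to 0.164). G1/S and S phase genes were higher there by 1.40 (0.98 to 1.95) over 8 measured genes and G2/M genes by 2.61 (1.83 to 3.22) over 6. The share of cells with at least 3 G2/M UMIs at 1500 UMIs was 2 of 100 cells (0.240 to 7.04%) at E85 and 8.45% (3.16 to 17.5) in the library labelled E125, with overlapping intervals, and 5.61% and 14.1% unthinned. The dissociation stress list stood at −0.55 (−0.91 to −0.11) and stromal markers at 1.63 (1.05 to 2.20).

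Mural-like cells carried more smooth muscle contraction RNA at E105, with a median of 0.48 (0.22 to 0.75) and all 15 measured members higher, and in the library labelled E125, with 0.72 (0.48 to 0.96) against E85. The other classes stood at 0.30 and 0.85, and gene by gene mural-like cells differed from them by 0.23 and −0.38. Myoid markers were higher in the same cells, by 0.77 (0.35 to 1.09) and 0.86 (0.64 to 1.30), and in the library labelled E125 so were stromal markers, by 0.64 (0.34 to 0.92). MYH11, smooth muscle myosin, was 17.0 times as high there (12.5 to 23.6) and also at least 2 times higher in every other measured class. The immunoproteasome genes PSMB8 and PSMB9 had ratios of 0.0570 (0.0244 to 0.119) and 0.0992 (0.0678 to 0.143). At E105 against E85 ID4 had a ratio of 6.28 (2.71 to 17.9) and RGS4 of 0.307 (0.193 to 0.479). Lymphoid-like cells were a different mix of clusters in each library. Cluster 3, led by JCHAIN and PAX5, held 102 of 373 cells at E85 and 71 of 578 at E105, and cluster 26, led by IL26, ICOS and TRDC, 32 of the E85 cells and 52 of 107 in the library labelled E125. Cluster 9, led by CD40LG and RHEX, made up 1.90% of all E85 cells and 3.48% of E105 cells. In this class G2/M genes were lower at E105, at −0.34 (−0.48 to −0.19), whereas G1/S and S phase genes stood at 0.16 (−0.11 to 0.33), at percentile 98.3. Fetal growth and imprinted genes stood at −0.86 (−1.06 to −0.16). RHEX, which also leads cluster 9, was 5.12 times as high (3.52 to 7.69) and the inhibitory receptor KLRG1 4.06 times (3.07 to 5.44). The protease CTSS had a ratio of 0.150 (0.128 to 0.176) and C1R of 0.127 (0.103 to 0.155), although with each library clustered on its own their log2 ratios were −0.47 and −0.09. The cytokine IL10 had a ratio of 0.101 (0.0647 to 0.153). IDO1 had 202.5 CPM at E85 and 0 UMIs at E105, at least 195.0-fold lower. IDO1 is also among the leading genes of unnamed cluster 18, with CLEC9A and CXCL9. For these lower genes a change within lymphoid-like cells cannot be told apart from a different set of cells so named. Macrophage markers were lower in the same cells, with a median of −2.02 (−2.64 to −1.19), as were stromal markers, with −0.62 (−0.96 to −0.41). In the library labelled E125, granzyme gene GZMA had 0 UMIs against 63.1 CPM at E85, at least 10.3-fold lower. Macrophage markers stood at −2.37 (−2.85 to −1.97) in these cells, or at −0.90 with the 2 of 5 members at 0 UMIs set to the 3-count floor, and stromal markers at 1.91 (1.55 to 2.27).

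Some differences ran through all 5 classes that each library held in number. Nuclear-encoded oxidative phosphorylation genes were lower in the library labelled E125 than at E85 in stromal-like (−0.85), mural-like (−0.70), lymphoid-like (−0.66), macrophage-like (−0.61) and endothelial-like cells (−0.48), each at or below percentile 0.06, with 17 of the 30 listed genes found by symbol. At E105 against E85 the same list lay between −0.06 and 0.08. In the library labelled E125 against E85, 2816 genes had at least 20 UMIs in every class. Of these, 101 were at least 2 times higher and 16 at least 2 times lower in all 5 classes. If classes varied independently, 0.06 and 0.00 would be expected. The classes share their libraries, so they cannot be independent, and these expected counts are no test. Their log2 ratios correlated at 0.58 to 0.78 between pairs of classes. At E105 against E85 the same rule gave 13 higher and 1 lower of 2334 genes, with JUN among those higher, and correlations of 0.18 to 0.64. These counts were made after the values were seen. A gene named above for 1 class can therefore reflect its library as well as its class.

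**Figure D4:**
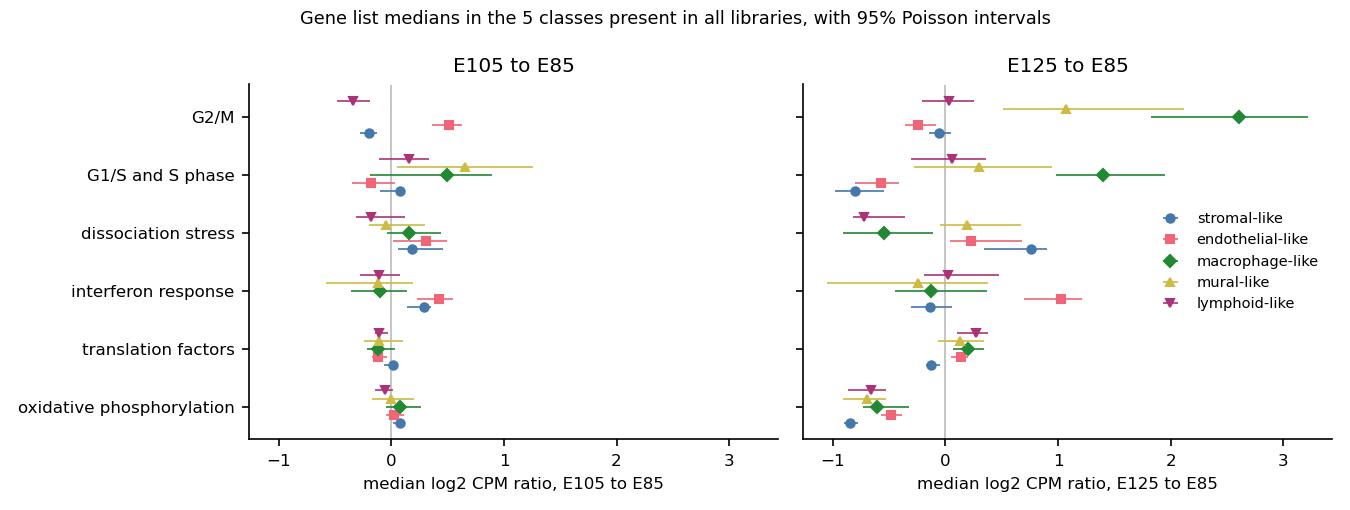
Median log2 CPM ratio (horizontal axis) of 6 gene lists (vertical axis) in the 5 classes present in every library, at E105 against E85 (left) and in the library labelled E125 against E85 (right), with 95% intervals from Poisson draws. Oxidative phosphorylation lies between −0.85 and −0.48 in all 5 classes on the right and between −0.06 and 0.08 on the left.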

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

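The tests on the library labelled E125 and on AMH, the test of depth on the lower shared genes, and the choice to look for genes shared by all classes, were made only after the results were seen.

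The library labelled E125 drew attention because cells outside the compared classes stood above the limit that a count of 0 allows in another library. The ZP3/FIGLA-led cells were 1.667% of it, and cluster 33, led by KCNK12, FST and HSD17B1, was 8.405%. Over the cells of the 5 shared classes there were also 3 features at 20 CPM or more in both other libraries that had 0 UMIs in it, against 0 such features when the library of E85 or of E105 took its place. Over all kept cells there were 2, against 0 and 0. Separately, the G2/M list differed in direction between classes at E105 against E85. It stood at 0.51 in endothelial-like and 0.37 in Sertoli-like cells, and at −0.34 in lymphoid-like and −0.20 in stromal-like cells. The G1/S list did not follow it, at −0.18, 0.21, 0.16 and 0.08 in these classes, in the same order. The difference between classes was not tested, since each stage has 1 library.

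The first pattern is the set of cells and genes in the library labelled E125, with oocyte genes high, Sertoli genes low and SRY at 0 UMIs. Loss of germ and Sertoli cells from a fetal testis adds no cells, and a later stage of testis alone would hold few ZP3/FIGLA-led cells, as at E85 and E105, so their 1.667% argues against each as the whole explanation. A fetal testis with some cells of another gonad mixed in would keep its Sertoli-like cells, but those outside cluster 6 were 0.0137% of the library, and the 6.22% so named with each library clustered on its own had 76.0 CPM of SOX9 against 328 at E85. A swap of labels within the series would move names and not cells. Every label of the series names fetal testis, so after such a swap these cells would still be labelled testis. A swap within the series alone therefore cannot account for the pattern. Whether stages were swapped in addition stays open, and the share of ZP3/FIGLA-led cells under the other labels cannot decide on it. In the main clustering the highest such share was 0.029%. Without the library labelled E125, 0.276% of E85 cells were so named (0.118% without the top 6% of doublet scores). Those cells had 0 UMIs of ZP3 and of FIGLA. A single wrong label or a swap with an outside sample, such as a fetal ovary, needs no partner in the series, may account for the 3 features at 0 UMIs, and stays open, as does a difference of stage in addition to it, which was not tested.

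The next pattern is the 101 genes at least 2 times higher and 16 at least 2 times lower in all 5 shared classes in the library labelled E125 against E85. After thinning to a common depth 69.2% of them remained, 74 of the 101 higher genes and 7 of the 16 lower ones (43.8%). The genes that remained did not rest on the greater weight of deep cells in the sums. Thinning keeps the expected proportions within a cell but adds counting noise around a cut that must hold in all 5 classes. The losses therefore cannot decide on other effects of a difference in UMIs per cell, which stay open for both directions. Free RNA of 1 of these 5 classes would leave a steep gradient between them. The lowest class level was 0.517 of the highest in the median higher gene and, in E85, 0.421 in the median lower gene. For these genes as a set the values argue against such a source, but it stays open for the 3 higher and 2 lower genes where that ratio was under 0.1. Free RNA of a cell type outside the 5 classes could reach all of them alike. The ratio cannot decide on that source, which stays open for all these genes. A gene was counted only with at least 20 UMIs in every class, so genes with a steep gradient were less likely to enter. The ratio cannot decide on genes left out in this way. Stromal markers were higher by 2.21 in endothelial-like, 1.91 in lymphoid-like, 1.63 in macrophage-like and 0.64 in mural-like cells. Free stromal RNA or mixed cells therefore stay open for genes outside the counted set. A library or batch difference rather than stage cannot be told apart from stage, because there is 1 library per stage, and a difference of tissue also stays open.

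The last pattern is the higher AMH in E105 Sertoli-like cells. In cells thinned to 1 depth the ratio was 3.194 (3.146 to 3.244), so it did not rest on the greater weight of deep cells in the sums. Thinning keeps the expected proportions within a cell. It therefore cannot decide on other effects of a difference in UMIs per cell, which stay open. A different mix of clusters is argued against by the ratio within cluster 0, 3.187 (3.152 to 3.222). More free AMH RNA as the source of most of the gain is argued against, because the highest gain of another class, mural-like, was 8.39% of the gain in Sertoli-like cells. AMH was nevertheless higher at E105 in each of the other classes compared. It went from 48.9 to 443.3 CPM in mural-like, 58.5 to 185.9 in germ-like and 59.0 to 107.1 in stromal-like cells. A rise in free AMH RNA or mixed cells beside the gain in Sertoli-like cells therefore stays open. Stage stays open as a biological difference, untested, as does any other difference between these animals or libraries.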

How the results depend on the processing

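Removal of the top 6% of doublet scores and clustering without the library labelled E125 were chosen only after the data were seen. No paired analysis was possible because each stage has 1 library, and for the same reason no library could be left out within a stage. Of 2427 list medians under an alternative 2180 stayed within their interval, 226 moved beyond it and 21 changed sign, over 216 medians. For named genes 851 of 943 values stayed, 90 moved and 2 changed sign. Of 184 shares of cells 134 stayed and 50 moved, and of 52 proliferation shares 20 stayed and 32 moved. The cause was not tested for the values below, except where the setting itself shows it. The thinning depth is set from the cells kept, so it moves with every choice of cells.

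TMM scaling takes the median of all genes in germ-like cells from 0.21 to −0.03, and medians near 0.21 then fall to about 0 or below. In germ-like cells at E105 against E85 it gave 0.16 for G1/S and S phase, 0.18 for undifferentiated spermatogonia, −0.08 for G2/M, −0.05 for the piRNA pathway, −0.14 for oxidative phosphorylation, −0.04 for translation factors (0.20 in the main analysis), −0.10 for dissociation stress (0.14) and −0.07 for DAZL. In Sertoli-like cells it gave −0.01 for Sertoli cell function and −0.02 for FSHR. Translation factors became 0.03 in lymphoid-like cells at E105 against E85 (−0.11), −0.08 there in E125 against E105 (0.24) and 0.03 in stromal-like cells in E125 against E105 (−0.11). The stromal-like collagen list in E125 against E85 became 1.22.

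The G1/S list of germ-like cells was 0.18 in thinned cells and 0.17 as a mean over cells, and their G2/M list 0.04 in thinned cells. The stromal-like collagen list at E105 against E85 was 0.38 with at least 100 UMIs and 0.75 without the library labelled E125. In E125 against E85 it was 1.57 with at least 100 UMIs, 1.66 with each library clustered on its own, 0.93 as a mean over cells and 1.22 with the stricter filter. Both collagen medians stayed above 0 under every alternative run. Mural-like G2/M in E125 against E85, 1.07 in the main analysis on 6 genes, was −0.55 with each library clustered on its own, −1.62 with the stricter filter and −0.28 without the top 6% of scores. In thinned cells and as a mean over cells, mural-like interferon response in E125 against E105 became 0.66 and 0.10 (from −0.80), and smooth muscle contraction −0.02 and −0.01 (from 0.16). Lymphoid-like glycolysis in E125 against E85 became 0.07 with at least 100 UMIs and 0.03 as a mean over cells (from −0.29). Macrophage-like glycolysis in E125 against E105 became −0.12 in thinned cells (from 0.25). With the stricter filter stromal-like interferon response at E105 against E85 became −0.06 (from 0.29) and the mural-like insulin-like growth factor list −0.01 (from 0.59).

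Shares of cells depended on the filter, by construction, since classes differ in UMIs per cell. With no filter Sertoli-like cells were 34.2%, 24.7% and 0.108% in the order E85, E105 and E125, stromal-like cells 33.9%, 43.7% and 62.7%, germ-like cells 5.41% at E85 and ZP3/FIGLA-led cells 2.35% of the library labelled E125. With the stricter filter Sertoli-like cells were 68.9%, 55.7% and 0.0%, stromal-like cells 6.77%, 17.6% and 58.9%, germ-like cells 5.02% and 1.93%, and ZP3/FIGLA-led cells 2.06%. At Leiden resolution 2 Sertoli-like cells were 0.027% of the library labelled E125 and stromal-like cells 29.7% and 37.1% of E85 and E105. With each library clustered on its own the library labelled E125 had 6.22% Sertoli-like and 20.3% stromal-like cells. Stromal-like cells were 34.4% and 45.7% of E85 and E105 without the top 6% of scores, and 45.0% of E105 without the library labelled E125.

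For germ-like cells the share with TOP2A at E85 and E105 was 67.3% and 74.0% unthinned, 61.3% and 74.2% with the stricter filter, and 11.1% and 12% with no filter. At E85 it was 53.4% without the library labelled E125 and 56.5% without the top 6% of scores, and at E105 43.2% with doublets kept. The share with at least 3 G2/M UMIs was 27.6% and 37.6% with no filter. At E105 it was 100% with the stricter filter, with doublets kept, without the top 6% of scores and without the library labelled E125, and the share with at least 2 UMIs was also 100%. At E85 it was 98.3% with doublets kept and 96.8% unthinned, and 97.3% had at least 5 UMIs. Germ-like cells at E105 numbered 96, which limits the precision of these shares.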

Other observations

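The genes in this part were read only after the results of the library labelled E125 were seen.

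Over all kept cells FST stood at 4.25 CPM at E85, 2.40 at E105 and 240.6 in the library labelled E125. HSD17B1, an enzyme of oestradiol synthesis, stood at 19.3, 11.2 and 97.1 CPM, and CYP19A1, the aromatase gene, had 0, 0 and 338 UMIs. LHX8, a factor of oocyte development, stood at 1.42, 0.586 and 142.5 CPM. BMP15, an oocyte growth factor, had 1, 0 and 369 UMIs, and WNT4, a gene of ovarian fate, had 2, 3 and 146.

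Within cluster 33, which no cell of E85 or E105 entered, FST stood at 1288 CPM, HSD17B1 at 469 CPM, CYP19A1 at 43.0 CPM, AMH at 170.4 CPM and SOX9 at 13.4 CPM. Cells like those of the rete or duct epithelium made up 1.15% of E85, 0.375% of E105 and 0.041% of the library labelled E125.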
